A study of Cucurbita pepo with 12 samples.

How the data were processed

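Total RNA was extracted from root, leaf and pollen of zucchini plants. Strand-specific mRNA libraries were made with a TruSeq kit and sequenced as single reads of 75 bp on a NextSeq 500, per the series design text. The text states that 3 biological replicates per treatment were extracted, while the labels give 1 library for each of the 3 tissues and 4 treatments. Whether RNA was pooled is not given in the sources used here. Plants were germinated for 10 days before transfer to 500 g of soil, 1 per pot. STAR is named as the aligner, with a reference transcriptome from a cucurbit genome database, in the series design text. The submitters' processing notes also name cutadapt and StringTie. Versions and settings of these tools are not given in the sources used here.

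The deposited table gives FPKM per gene and library, as normalized by the authors, for 27868 genes. It holds no read counts, so no count model was used. Low FPKM values of a gene are multiples of what 1 read is worth in that library. The relative depth of libraries was therefore estimated from the ratios of values between 0.05 and 1.5 FPKM in pairs of libraries, which pile up at ratios of whole numbers up to 4. Within a tissue, estimates from different pairs closed within 0.005 on the log2 scale. The step from root to leaf and to pollen had no such check. Absolute depth is unknown, so no counting interval is given for single values. Exact zeros can be failed estimates. Genes at 0 in a library are said to be listed at 0, and no fold is given for them. Sets of genes with identical values in all libraries held 227 genes in 108 sets. They may be gene models whose reads could not be told apart, which was not tested. IDs with the LG00 prefix made up 117 of these 227 genes.

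Values were analysed as log2(FPKM + 1), which understates the change of genes with low values. Within a tissue, genes with a mean of at least 1 FPKM over its 4 libraries were kept: 20985 in root, 20833 in leaf and 11185 in pollen. With 1 library per group, differences were described by size. Genes at or past 2.3 were counted per direction, the threshold the series design text names for log2 FPKM, which is a 4.92-fold difference in FPKM + 1. The SD over genes of the log2 difference described the distance between 2 libraries. Overlaps of genes past the threshold in the same direction were set beside n1 × n2 / N, from each list's length among the N genes kept in both comparisons. This value gives every gene the same chance of passing. Genes with the LG00 prefix, for one, made up 21.3% of the leaf genes past 2.3 under nanoparticles, against 4.33% of all leaf genes kept. Where comparisons shared a control, overlaps were also set beside 100 sets of simulated unchanged libraries. Their noise was drawn within 20 expression bins from the differences of the closest pair of libraries of the tissue. This pair was control and nanoparticles in root and leaf, and bulk CuO and CuSO4 in pollen, so the noise may hold treatment effects.

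Tissues were compared with limma 3.58.1 (R 4.3.3) on all 12 libraries, with treatment as a block, empirical Bayes moderation with a trend, Benjamini-Hochberg adjusted p under 0.05 and at least 1 on the log2 scale. Genes needed a mean of at least 1 FPKM in at least 1 tissue. Treatment effects shared by tissues were fitted on the 12 libraries with tissue as a block, at an adjusted p under 0.05, for genes with a mean of at least 1 FPKM in every tissue. The error of that fit is the difference of effects between tissues. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

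The tests, thresholds and the rule for the genes named were set before the data were examined. For each treatment in each tissue and for direct comparisons, genes were ranked by log2 change among those with at least 5 FPKM in the higher library. For tissues, they were ranked by mean level among genes higher than in both other tissues, and for shared effects by adjusted p. Because 0 gene IDs of the table occur in the RefSeq gene table of assembly ASM280686v2, at most the first 2 genes per direction are named. For the same reason the gene lists planned for copper transport, metal binding, oxidative stress, photosynthesis, cell wall, defence and tissue markers could not be applied, and no gene function is reported. The gene called without the pollen libraries, also on or off in both root and leaf, was singled out after its values were seen.

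The steps were tested on simulated data. With the noise of the closest pair, 96.6% of genes changed by 3 on the log2 scale in root, 96.8% in leaf and 98.1% in pollen passed 2.3. The changed genes were drawn from those with a mean log2(FPKM + 1) at or above that of 5 FPKM, and were only raised. Falls, and changes of genes at lower levels, were not simulated. The share of unchanged genes past 2.3 is set by that pair, so the simulation gives no separate rate of false calls. For leaf against root, calls used an adjusted p under 0.05 without the minimum of 1 on the log2 scale. Over 23751 genes, limma recovered 73% of genes changed by 2, with 12 false calls, and 12% of those changed by 1, with 2. For an effect of nanoparticles shared by tissues over 9432 genes, it recovered 12.5% of genes changed by 1, 79.5% of those changed by 2 and 97.5% of those changed by 4.

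Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 10 FPKM, a median shift and quantile normalization between libraries, thresholds of 1 and 3, fits without blocks, without trend or on 8 libraries, and fits leaving out each treatment or tissue. After the data were seen, counts were added without genes listed at 0, with 1 gene of each identical set, and, for direct comparisons, with threshold 1 and quantile normalization.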

Results

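Messenger RNA was sequenced from root, leaf and pollen of zucchini (Cucurbita pepo, cultivar Costata Romanesco) grown in soil without added copper or with 1 of 3 copper materials. The materials were copper oxide (CuO) nanoparticles, CuO of larger particle size (bulk CuO) and copper sulfate pentahydrate (CuSO4). CuO was added at 100 mg/kg of soil and the sulfate at 320 mg/kg, each giving about 80 mg/kg of copper, and the plants grew for 60 days until they flowered. Each of the 12 combinations of tissue and treatment had 1 library, so differences between treatments within a tissue have no replicate check and no p-value. The 4 libraries of a tissue differ in treatment, and they serve as its replicates where tissues are compared.

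The table held 27868 genes in FPKM (fragments per kilobase of transcript per 1e6 reads), of which 1436 were listed at 0 in every library. Root libraries had 20550 to 20881 genes at 1 FPKM or more, leaf libraries 19676 to 20957 and pollen libraries 10309 to 11569. Read totals were not in the table. The spacing of the lowest values gave depths relative to the root control library of 0.917 to 1.10 in root, 0.862 to 0.933 in leaf and 0.635 to 0.742 in pollen. Gene IDs are printed as the table gives them, because neither it nor the gene table used here pairs them with names. No gene function is given for that reason, and at most 2 genes per direction are named for each comparison.

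In root, the comparison of each copper material with the untreated plants asked which transcripts differ below ground, where the material was added. Bulk CuO differed most from the control library: 175 genes were higher and 76 lower at or past 2.3 on the log2(FPKM + 1) scale, the submitters' threshold, among 20985 genes. CuSO4 had 33 genes higher and 72 lower, and nanoparticles 30 higher and 22 lower. Most of the leading genes in root were listed at 0 in 1 of the libraries compared. Cp4.1LG00g13940 stood at 93.1 FPKM in control root and 93.3 FPKM under bulk CuO, and was listed at 0 under nanoparticles and under CuSO4. Leaf gave the same arrangement, with 75.0 FPKM in the control, 80.6 FPKM under bulk CuO and 0 under nanoparticles and CuSO4. Cp4.1LG18g05970 was listed at 0 in control and bulk CuO roots and at 33.1 FPKM under nanoparticles and 31.6 FPKM under CuSO4. Cp4.1LG00g04700 was listed at 0 in the nanoparticle root library and at 31.5 FPKM in control root. Cp4.1LG19g07750 was lower under bulk CuO, at 0.082 FPKM against 14.8 FPKM in control root, a log2 change of -3.87. Under bulk CuO, Cp4.1LG00g04280 and Cp4.1LG11g09880 both stood at 22.997 FPKM against 0 in the control. Their values were equal in 11 libraries and stood at 30.65 and 30.61 FPKM in the nanoparticle root library. Their levels are uncertain if reads were shared between them, which was not tested. Under CuSO4, Cp4.1LG14g02750 stood at 34.8 FPKM and was listed at 0 in the other 3 root libraries, and Cp4.1LG16g01940 was listed at 0 against 24.1 FPKM in the control. Without genes listed at 0 in either library, 24 genes were past the threshold for nanoparticles (19 higher and 5 lower), 217 for bulk CuO (152 and 65) and 70 for CuSO4 (21 and 49).

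In leaf, bulk CuO and CuSO4 were far from the control library and nanoparticles were close to it. Under bulk CuO 951 genes were higher and 735 lower among 20833, and under CuSO4 595 were higher and 695 lower, against 21 higher and 26 lower under nanoparticles. On the log2(FPKM + 1) scale, used for every ranking here, Cp4.1LG17g09870 had the largest increase over the control library under both materials. It went from 2.45 FPKM in control leaf to 1449 FPKM under bulk CuO and 353 FPKM under CuSO4, log2 changes of 8.71 and 6.68. Under nanoparticles it stood at 0.327 FPKM. Cp4.1LG11g04820 went from 0.193 FPKM to 329 FPKM under bulk CuO and 120.0 FPKM under CuSO4, with 0.191 FPKM under nanoparticles. Its FPKM ratio to control was larger than that of Cp4.1LG17g09870 under both materials, so their order depends on the value added before the log. The largest decrease under bulk CuO was that of Cp4.1LG03g10370, from 757 FPKM to 2.10 FPKM, a log2 change of -7.94, with 36.1 FPKM under CuSO4 and 654 FPKM under nanoparticles. Cp4.1LG04g08390 went from 282 FPKM to 0.85 FPKM under bulk CuO and 4.11 FPKM under CuSO4, with 120.1 FPKM under nanoparticles. The largest decreases under CuSO4 were those of Cp4.1LG10g07120, from 184 FPKM to 0.602 FPKM, and of Cp4.1LG01g05010, from 174 FPKM to 0.80 FPKM, which stood at 1.42 and 10.8 FPKM under bulk CuO and at 103 and 178 FPKM under nanoparticles. All 4 leading genes of the nanoparticle comparison were listed at 0 in 1 library: Cp4.1LG01g00090 went from 0 to 27.8 FPKM, Cp4.1LG10g07140 from 0 to 14.3 FPKM, Cp4.1LG00g09790 from 83.3 FPKM to 0 and Cp4.1LG00g13940 from 75.0 FPKM to 0. Of the 47 genes past the threshold under nanoparticles, 31 were listed at 0 in 1 of the libraries compared, and 4 higher and 12 lower genes were left without them. Bulk CuO had 840 higher and 678 lower genes without those listed at 0, and CuSO4 547 and 626.

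The balance of directions in leaf depended on how libraries were scaled. Genes of the bulk CuO leaf library lay at a median of 0.18 above the control on the log2 scale. As deposited, 56.4% of the genes past the threshold were higher under bulk CuO. This share was 45.7% after each library was shifted to a common median (730 higher and 867 lower) and 47.5% after quantile normalization (755 higher and 836 lower). Relative to the other genes of the library, higher genes therefore did not outnumber lower ones.

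**Figure D1:**
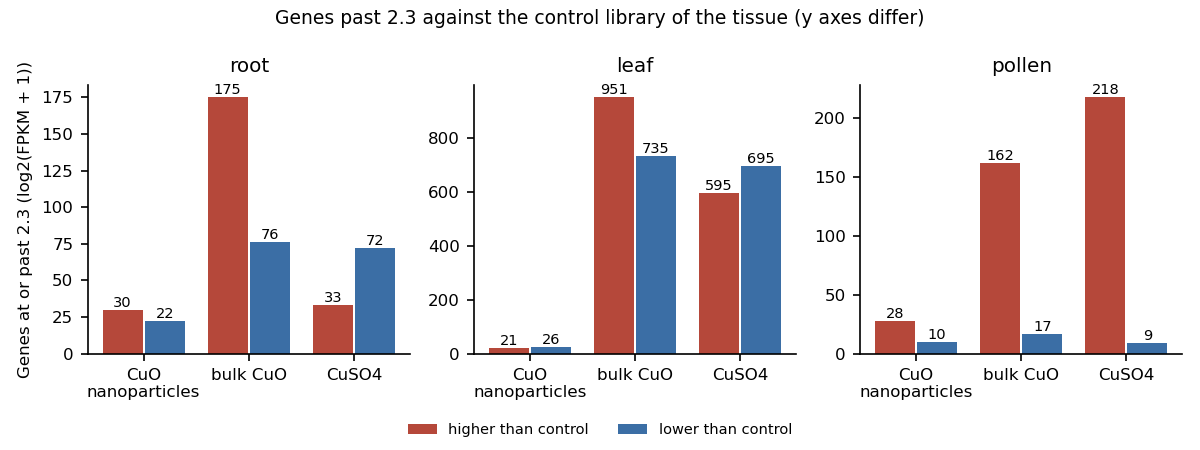
Number of genes at or past 2.3 on the log2(FPKM + 1) scale against the control library of the same tissue, higher (red) and lower (blue), for each copper material in root, leaf and pollen; each bar compares 1 treated library with 1 control library, and the y axes differ. Leaf under bulk CuO had 951 genes higher and 735 lower, while pollen under CuSO4 had 218 higher and 9 lower; in leaf under bulk CuO the excess of higher genes turned around after a median shift or quantile normalization.

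**Figure D2:**
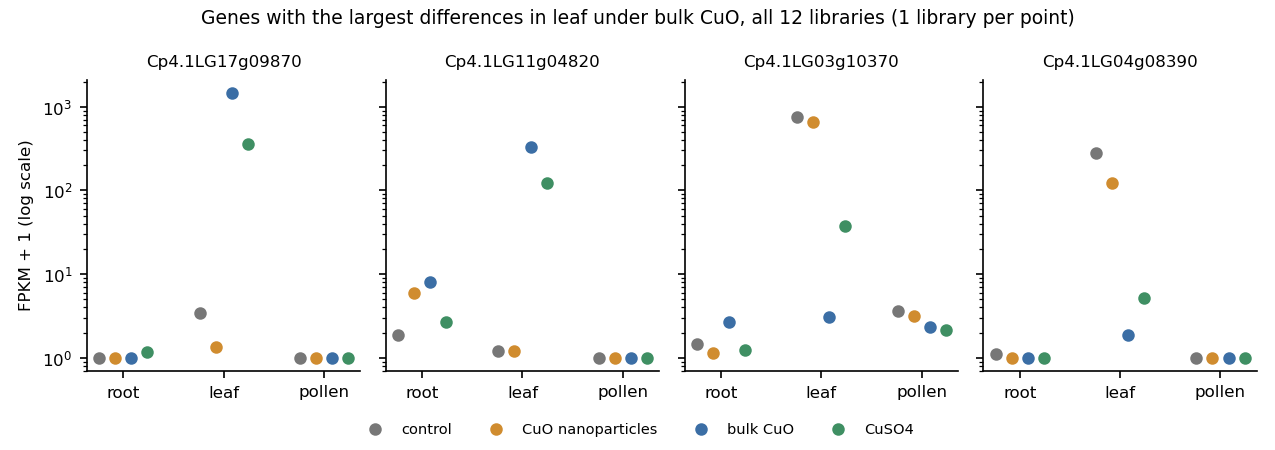
FPKM + 1 on a log axis of the genes with the largest increases (Cp4.1LG17g09870 and Cp4.1LG11g04820) and decreases (Cp4.1LG03g10370 and Cp4.1LG04g08390) in leaf under bulk CuO, in all 12 libraries; each point is 1 library, coloured by treatment. The genes were chosen for their difference under bulk CuO; Cp4.1LG04g08390 stood at 282 FPKM in control leaf, 120.1 under nanoparticles, 0.85 under bulk CuO and 4.11 under CuSO4.

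In pollen, nearly all genes past the threshold under bulk CuO and CuSO4 were higher than in the control library. Among 11185 genes, 162 were higher and 17 lower under bulk CuO, 218 higher and 9 lower under CuSO4, and 28 higher and 10 lower under nanoparticles. Cp4.1LG02g02060 went from 0.202 FPKM in control pollen to 132 FPKM under bulk CuO and 112 FPKM under CuSO4, log2 changes of 6.79 and 6.56, and stood at 0.435 FPKM under nanoparticles. Cp4.1LG13g02790 was listed at 1023 FPKM under bulk CuO and at 0 in the other 11 libraries of the series. Cp4.1LG12g07900 was listed at 379 FPKM under nanoparticles and 741 FPKM under CuSO4, and at 0 in all others. Cp4.1LG10g00960 was listed at 0 in control pollen and at 33.3 FPKM under nanoparticles. Among the lower genes, Cp4.1LG03g18230 went from 42.1 FPKM to 0.246 FPKM under CuSO4, a log2 change of -5.11. Cp4.1LG09g11020 stood at 17.7 FPKM in control pollen and was listed at 0 in all 3 treated pollen libraries. Cp4.1LG00g12410 was listed at 0 under nanoparticles against 44.7 FPKM in the control. Cp4.1LG02g14670 and Cp4.1LG10g08750 were listed at 0 under bulk CuO, against 34.9 and 22.9 FPKM. Without genes listed at 0 in either library, 106 genes were higher and 2 lower under bulk CuO, 167 higher and 2 lower under CuSO4, and 13 higher and 1 lower under nanoparticles. The nanoparticle pollen library lay at a median of 0.12 above the control on the log2 scale, and after a median shift it had 26 genes higher and 11 lower.

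The copper materials were also compared with each other, so that no control library entered. In leaf, 905 genes were higher and 591 lower under bulk CuO than under nanoparticles, 511 higher and 525 lower under CuSO4 than under nanoparticles, and 72 higher and 161 lower under CuSO4 than under bulk CuO. On the log2(FPKM + 1) scale, Cp4.1LG17g09870 had the largest increase from nanoparticles to both other materials in leaf, and Cp4.1LG03g10370 the largest decrease from nanoparticles to bulk CuO. Between bulk CuO and CuSO4 leaves, Cp4.1LG16g08670 was listed at 0 and 65.0 FPKM, and Cp4.1LG05g02690 at 128 FPKM and 0. In root, 300 genes were higher and 189 lower under bulk CuO than under nanoparticles, 47 higher and 72 lower under CuSO4 than under nanoparticles, and 84 higher and 172 lower under CuSO4 than under bulk CuO. Cp4.1LG03g18220 stood at 0.222 FPKM under nanoparticles and 124 FPKM under bulk CuO in root, a log2 difference of 6.67, with 20.8 FPKM in the control. Cp4.1LG20g07200 showed the opposite, with 115 FPKM under nanoparticles and 1.14 FPKM under bulk CuO, a log2 difference of -5.76, and 12.2 FPKM in the control. In pollen, 113 genes were higher and 19 lower under bulk CuO than under nanoparticles, 108 higher and 14 lower under CuSO4 than under nanoparticles, and 27 higher and 14 lower under CuSO4 than under bulk CuO. Quantile normalization turned the balance between nanoparticles and bulk CuO in leaf to 705 higher and 753 lower, and that between nanoparticles and CuSO4 in root to 61 higher and 60 lower.

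The standard deviation (SD) over genes of the log2 difference gave the distance between 2 libraries. In leaf it was 0.392 between control and nanoparticles and 0.676 between bulk CuO and CuSO4, and it lay between 1.10 and 1.27 for the other 4 pairs. The closest pairs in pollen were these 2 as well, with 0.427 between control and nanoparticles, 0.393 between bulk CuO and CuSO4 and 0.601 to 0.673 for the other pairs. In root the pairs of control, nanoparticle and CuSO4 libraries lay at 0.455 to 0.548, and the bulk CuO library lay at 0.706 to 0.850 from each of them. No pair of libraries was a replicate pair, so these distances have no baseline of their own. They also depended on the value added before the log: with 0.1 in place of 1 the distance between control and nanoparticles was 0.588 in leaf and 0.713 in pollen, and with 5 it was 0.256 and 0.246.

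**Figure D3:**
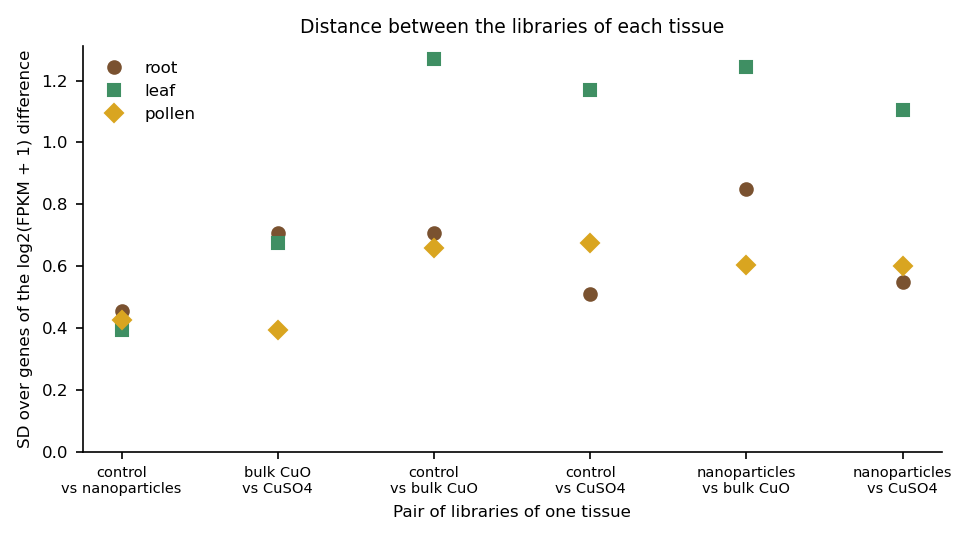
SD over genes of the log2(FPKM + 1) difference for each of the 6 pairs of libraries in root (circles), leaf (squares) and pollen (diamonds); each point is 1 pair. Leaf pairs that join control or nanoparticles to bulk CuO or CuSO4 lie at 1.10 to 1.27, and the pair of control and nanoparticles at 0.392.

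Genes past the threshold were then compared between treatments. Bulk CuO and CuSO4 shared 897 genes in leaf, 428 higher and 469 lower under both, and 1 gene went in opposite directions. Independent lists of the same lengths would share 51.7 genes, and unchanged libraries simulated against 1 control shared 16.1 on average. In pollen these materials shared 124 higher and 5 lower genes, against 3.17 for independent lists and 14.9 for simulated unchanged libraries. In root they shared 13 higher and 18 lower genes, against 0.536 and 13.5. Nanoparticles shared 16 genes with bulk CuO and 16 with CuSO4 in root, 20 and 24 in leaf, and 24 and 27 in pollen. In root, 2 genes also went in opposite directions under nanoparticles and bulk CuO, against 0.292 for independent lists, and at threshold 1 more genes went in opposite directions (156, against 47.5) than in the same one (127, against 49.2). Simulated unchanged libraries shared up to 23, 26 and 27 genes in root, leaf and pollen. In root and leaf their noise was taken from the difference between the control and nanoparticle libraries itself, so there they give no separate baseline for the nanoparticle overlaps. In pollen it was taken from the difference between bulk CuO and CuSO4, so there they give none for the overlap of these materials. In leaf the simulated 16.1 lies below the 51.7 of independent lists, so it is no chance level for the long lists of bulk CuO and CuSO4. Without genes listed at 0, nanoparticles shared 0 genes with each other material in root, where 2 were opposite to bulk CuO, 5 with bulk CuO and 9 with CuSO4 in leaf, and 8 and 13 in pollen. Without them bulk CuO and CuSO4 shared 16 in root. Each tissue has 1 control library, so part of every excess may come from that shared control. Cp4.1LG17g09870 and Cp4.1LG11g04820 were among the higher genes under both materials in leaf, and Cp4.1LG02g02060 in pollen.

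Few genes were past the threshold in the same direction in different tissues under the same treatment. Independent lists give every gene the same chance of passing, so an excess over them was described and not tested. Under bulk CuO, root and leaf shared 6 higher and 17 lower genes, against 4.67 and 1.81 for independent lists, and 16 went in opposite directions, against 6.24. Under CuSO4 they shared 1 higher and 11 lower genes, against 0.455 and 1.53. Under nanoparticles they shared 3 higher and 4 lower, against 0.0154 and 0.0110, or 1 gene without those listed at 0. In opposite directions root and leaf had 2 genes under CuSO4, against 1.70, and 2 under nanoparticles, against 0.0290. Leaf and pollen shared 9 genes under bulk CuO, against 3.49, and 7 under CuSO4, against 3.08. More genes went in opposite directions there, 20 under bulk CuO, against 4.02, and 23 under CuSO4, against 5.21. Without genes listed at 0, leaf and pollen shared 3 genes under bulk CuO, against 1.94, and 2 under CuSO4, against 2.06. Leaf and pollen shared 1 gene under nanoparticles, against 0.0119. Root and pollen shared 2 genes under nanoparticles, against 0.00568, 2 under bulk CuO, against 0.60, and 3 under CuSO4, against 0.0676. In opposite directions they had 1 gene under nanoparticles, against 0.0106, and 5 under CuSO4, against 0.445. Without genes listed at 0, the nanoparticle overlaps of pollen with root and with leaf were 0. Cp4.1LG00g13940, listed at 0 in both root and leaf, was 1 of the genes lower under nanoparticles and under CuSO4 in these tissues.

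Tissues were compared with limma over all 12 libraries, with treatment as a block. Of 23751 genes, 7959 differed between root and leaf at an adjusted p under 0.05 and at least 1 on the log2 scale, 4167 higher in root and 3792 higher in leaf. Higher values than in both other tissues were found for 3523 genes in root, 3447 in leaf and 2339 in pollen. Among those of root, Cp4.1LG11g07990 averaged 5029 ± 590.4 FPKM in root (SD, n = 4 libraries), 665 ± 522 FPKM in leaf and 11.5 ± 11.4 FPKM in pollen. Its log2 difference between root and leaf was 3.41 (SE 0.82, limma adjusted p = 0.00833). Cp4.1LG19g04650 averaged 3630 ± 2081 FPKM in root (SD, n = 4 libraries) and was at most 0.211 FPKM in any leaf and 0.285 FPKM in any pollen library. Among those of leaf, Cp4.1LG09g03060 averaged 6946 ± 2167 FPKM and Cp4.1LG01g13630 5265 ± 2211 FPKM (SD, n = 4 libraries). They reached at most 0.786 and 3.52 FPKM in root, with log2 differences between root and leaf of -12.33 (SE 0.31, limma adjusted p = 3.52e-08) and -10.48 (SE 0.23, limma adjusted p = 2.81e-08). Among those of pollen, Cp4.1LG07g06470 averaged 8567 ± 485 FPKM and Cp4.1LG07g05480 7557 ± 404 FPKM (SD, n = 4 libraries), and neither exceeded 0.289 FPKM in any root or leaf library. Their log2 differences between pollen and leaf were 12.95 (SE 0.14) and 12.77 (SE 0.13), both with limma adjusted p = 3.09e-11.

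Pollen differed from leaf in 18223 genes, 2886 higher and 15337 lower in pollen, and from root in 18236 genes, 2697 higher and 15539 lower. The median log2 difference over all genes was -1.79 between pollen and leaf and -1.78 between pollen and root. After a median shift the counts were 6938 higher and 7174 lower against leaf, and 7000 higher and 6609 lower against root. Quantile normalization gave 5865 higher and 7941 lower against leaf, and 5780 higher and 7698 lower against root. Between root and leaf, the median shift gave 3820 higher in root and 4063 higher in leaf, with a median log2 difference of 0.13 as deposited. The number of genes past 1 in each direction is therefore relative to the scaling, while the 6 genes named kept their direction and passed both criteria under every scaling. The p-values measure how far tissue differences vary between treatments, after treatment differences common to the tissues are removed. They do not measure the spread between plants of 1 treatment. It is not given in the sources used here whether a library held 1 plant or a pool of the 3 plants extracted per treatment.

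The last comparison asked whether any gene changed alike in all tissues under a copper material, with limma over the 12 libraries, tissue as a block, and the 9432 genes with a mean of at least 1 FPKM in every tissue. At an adjusted p under 0.05 it called 0 genes for nanoparticles, 0 for bulk CuO, 0 for CuSO4 and 0 for the mean of all copper materials. At an unadjusted p under 0.05 there were 48, 576, 416 and 257 genes. If no gene changed and the p-values were evenly spread, a share of about 0.05 of the 9432 genes would have such a p. Only the count for bulk CuO lay above that share, and the 48 for nanoparticles lay far below it. The fit uses 1 error for all treatments, which holds differences of effects between tissues. That share is therefore no firm baseline, and the 576 genes are not read as an excess. For bulk CuO, Cp4.1LG12g06530 had the smallest p, with a log2 difference of 1.95 (SE 0.31, limma adjusted p = 0.713). It stood at 27.0 FPKM against 8.37 FPKM in root, 9.87 against 0.617 FPKM in leaf and 6.72 against 1.69 FPKM in pollen. Cp4.1LG02g08300 had a log2 difference of -1.34 (SE 0.24, limma adjusted p = 0.713), with 91.7 FPKM under bulk CuO against 339 FPKM in control leaf. For CuSO4, Cp4.1LG13g03320 had a log2 difference of 0.95 (SE 0.19) and Cp4.1LG03g01320 of -1.41 (SE 0.32), both with limma adjusted p = 0.866. For nanoparticles, Cp4.1LG04g10670 had a log2 difference of 1.56 (SE 0.36) and Cp4.1LG12g01540 of -1.34 (SE 0.35), both with limma adjusted p = 0.9999. Without the pollen libraries, 1 gene passed, Cp4.1LG00g13940, for nanoparticles and for CuSO4 (limma adjusted p = 0.0091 each) and for the mean of all copper materials (limma adjusted p = 0.0301). It was listed at 0 in root and leaf under nanoparticles and CuSO4, so no fold is given and its p rests on the value added before the log. In pollen, left out of this fit, it stood at 10.2 FPKM in the control, 13.1 FPKM under nanoparticles, 7.78 FPKM under bulk CuO and 0 under CuSO4, and with pollen in the fit it did not pass. The gene was singled out after its values were seen.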

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

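Except for the tests of identical gene sets, of the share of genes at 0 with 10 or more reads expected, of other tissues' RNA in leaf and of genes shared by leaf and pollen, all tests below were chosen after the result was seen.

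Some genes lay on opposite sides of the control in leaf and pollen under the same material. Past the threshold of 2.3, 20 genes went in opposite directions in leaf and pollen under bulk CuO, against 4.02 for independent lists, and 23 under CuSO4, against 5.21. Root and pollen had 5 such genes under CuSO4, against 0.445. The counts depended on the settings. In the order leaf and pollen under bulk CuO, leaf and pollen under CuSO4, and root and pollen under CuSO4, they were 3, 2 and 2 with pseudocount 5 and 15, 19 and 3 without genes listed at 0. At threshold 1 they were 191, 241 and 43, against 103, 115 and 18.2 for independent lists. These differences between tissues were not tested, since each tissue and treatment had 1 library. Independent lists give every gene the same chance of passing. Genes past 2.3 in the same direction also exceeded them, with 9 against 3.49, 7 against 3.08 and 3 against 0.0676 in the same order. An excess over independent lists therefore does not by itself show opposite responses. Of 27 sets of 4 values examined for a library far from the other 3, 0 passed Dixon's critical value of 0.829, where chance gives about 1.35.

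Bulk CuO and CuSO4 leaves lay far from control and nanoparticle leaves. Scaling between libraries is not the cause of the distance, since 1591 genes were still past 2.3 under bulk CuO after quantile normalization. RNA of root or pollen is argued against too: transcripts at 100 FPKM or more in those tissues and under 1 FPKM in control leaf were present at 0.137% of their source level or less in the upper quartile, while the genes that were higher needed at least 228% in the lower quartile. A difference in sampling or handling that moved the same genes in leaf and pollen cannot be told apart from the treatments with 1 library per treatment; the overlap of leaf and pollen under bulk CuO was 2.58 times that of independent lists, but more genes went in opposite directions (20) than in the same one (9). The form of copper, and a difference in leaf age or growth between the plants, stay open and were not tested.

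Pollen under bulk CuO and CuSO4 had many genes higher and few lower. Leaf or root RNA in these libraries is argued against: abundant leaf and root transcripts were present at 0.506% of their source level or less in the upper quartile, where the higher genes needed 17.0% or more in the lower quartile. A deeper library is argued against for bulk CuO, whose depth was 0.986 times that of control pollen, and for the more abundant genes under CuSO4, a library 1.15 times as deep, since 98.9% of those past 2.3 with a mean of at least 10 FPKM were higher. Genes listed at 0 are not the cause, since at least 98.1% of the genes past 2.3 were higher without them. The treatments, the maturity of the pollen and other flower tissue stay open and were not tested.

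Genes listed at 0 in 1 library and at 5 FPKM or more in another of the same tissue numbered 75 in root, 227 in leaf and 88 in pollen. Reads shared between near-identical gene models may explain part of them: members of sets with identical values were more common among these genes, with an odds ratio of 4.48 (13 of 373 against 187 of 23378, Fisher's exact p = 1.8e-05, two-sided). Members of a set are listed at 0 together, so genes are not independent units and this p is too small. IDs with the LG00 prefix were also more common (64 of 373 against 1028 of 23378, odds ratio 4.50). The classes overlap, and they were not told apart. Of these genes, 44.9% had 10 or more reads expected in the library at 0, and counting error stays open for the others; over all 91370 values with 10 or more reads expected from the other libraries of the tissue, at 0 or not, counting error alone gives 0.107 zeros, against 233 observed. Differences in gene content between the plants of each treatment cannot be told apart from other causes: of 12 genes that were on or off in both root and leaf, 3 were off in the same treatments in both, and another assignment of leaf libraries to treatments gave 4. Cp4.1LG00g13940, 1 of those 3, was at 0 in nanoparticle root and leaf but at 13.1 FPKM in nanoparticle pollen (control pollen 10.2 FPKM). That value goes against its absence from the nanoparticle plants if the pollen came from the same ones. Under CuSO4 it was at 0 in root, leaf and pollen, so its absence from the CuSO4 plants stays open. The other 2 were at 0 in root and leaf under every copper material and in all pollen libraries, so pollen does not bear on them. Treatment effects were not tested.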

How the results depend on the processing

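Values are given in the order nanoparticles, bulk CuO and CuSO4 unless stated; the cause of a change was not tested except where the alternative itself sets it (a threshold, fewer genes). Counts against control moved by over 1.5 times with the pseudocount, a mean of at least 10 FPKM and the threshold in every tissue, and stayed within 1.5 times without a filter; overlaps, run under no other filter, moved with the threshold and pseudocount 5. The counts describe these settings; no direction was tested. Of 928 alternative values, 608 stayed close: a count or distance within 1.5 times, a share of higher genes within 10 percentage points, a fitted change on its side of the threshold. This total mixes unlike kinds. Of the counts of genes past 2.3, 56 stayed close and 61 moved, and of the overlaps 6 stayed close and 48 moved. Another 80 of the close values were fitted shared effects of named genes, none of which passed in the main fit. With a pseudocount of 0.1, the numbers of genes past the threshold against control were 150, 539 and 268 in root, 169, 2697 and 2281 in leaf, 214, 539 and 594 in pollen. With a pseudocount of 5, the numbers of genes past the threshold against control were 12, 90 and 29 in root, 15, 610 and 514 in leaf, 7, 38 and 43 in pollen. With a mean of at least 10 FPKM, the numbers of genes past the threshold against control were 17, 161 and 58 in root, 10, 987 and 851 in leaf, 14, 57 and 87 in pollen. With threshold 1, the numbers of genes past the threshold against control were 780, 2601 and 1082 in root, 502, 7275 and 6441 in leaf, 339, 955 and 1030 in pollen. With threshold 3, the numbers of genes past the threshold against control were 18, 67 and 33 in root, 19, 704 and 534 in leaf, 18, 79 and 94 in pollen. 

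Added after seeing the data, counts without genes listed at 0 were 24 in root, 16 in leaf and 14 in pollen for nanoparticles and 108 for bulk CuO in pollen. Direct comparisons in pollen then had 69 (nanoparticles and bulk CuO), 74 (nanoparticles and CuSO4) and 9 genes (bulk CuO and CuSO4). At threshold 1, also added, the direct comparisons in that order had 3699, 1401 and 2613 in root, 7258, 6198 and 2235 in leaf, 634, 741 and 209 in pollen. Keeping 1 gene of each identical set left every count against control within 1.5 times.

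The balance of higher and lower genes turned in these cases. Against control, the share of higher genes under bulk CuO in leaf was 44.4% with pseudocount 5, 46.8% with a mean of at least 10 FPKM, 45.7% with a median shift and 47.5% with quantile normalization, and under CuSO4 in leaf 53.8% with pseudocount 0.1 and 56.7% at threshold 1. For nanoparticles in root it was 44.4% at threshold 3. From nanoparticles to bulk CuO it was 47.5% in root at threshold 1 and 48.4% in leaf with quantile normalization, and from nanoparticles to CuSO4 50.4% in root with quantile normalization and 57.3% in leaf at threshold 1. Among genes that differ between tissues, the share higher in root than in leaf was 48.9% with pseudocount 5 and 48.5% with a median shift, and that higher in pollen than in root 51.4% with a median shift.

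Overlaps between treatments are given for nanoparticles with bulk CuO, nanoparticles with CuSO4 and bulk CuO with CuSO4. At threshold 1 they were 127, 168 and 408 in root, 292, 326 and 4925 in leaf, 240, 241 and 742 in pollen. With pseudocount 5 they were 3, 5 and 7 in root, 9, 12 and 344 in leaf, 0, 4 and 24 in pollen. Without genes listed at 0 they were 0, 0 and 16 in root, 5, 9 and 803 in leaf, 8, 13 and 91 in pollen. At threshold 1, independent lists gave 49.2, 20.02 and 67.0 in root, 80.7, 73.9 and 1158 in leaf, 22.0, 25.2 and 71.6 in pollen, and opposite directions were taken by 156, 30 and 49 in root, 42, 21 and 31 in leaf, 3, 9 and 6 in pollen. Overlaps of 1 treatment between tissues are given for root with leaf, root with pollen and leaf with pollen. They were, at threshold 1, 38, 12 and 7 for nanoparticles, 569, 65 and 163 for bulk CuO, 237, 29 and 131 for CuSO4. Pseudocount 5 gave 2, 0 and 0 for nanoparticles, 5, 0 and 0 for bulk CuO, 4, 0 and 0 for CuSO4. Leaving out genes listed at 0 gave 1, 0 and 0 for nanoparticles, 16, 2 and 3 for bulk CuO, 8, 2 and 2 for CuSO4. For these, threshold 1 gave 5.02, 2.34 and 1.25 for nanoparticles, 348, 39.5 and 125 for bulk CuO, 112, 9.98 and 114 for CuSO4 by independent lists, and 20, 7 and 6 for nanoparticles, 452, 84 and 191 for bulk CuO, 162, 43 and 241 for CuSO4 in opposite directions, which outnumbered the same direction in pollen with root and with leaf under bulk CuO and CuSO4. 

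The closest pair of each tissue was the same under all alternatives, and the farthest pair too except in pollen with pseudocount 0.1, where it was control and bulk CuO; the ratio of the most distant to the closest pair stayed within 1.5 times in each tissue. The distances themselves were less stable: 14 moved by over 1.5 times with pseudocount 0.1 or 5 (control and bulk CuO in pollen to 1.07 and 0.375, from 0.657). Pairs and ratios were run only with pseudocounts 0.1 and 5, quantile normalization and a mean of at least 10 FPKM, which gave 12 alternative ratios over the tissues. Tissue counts stayed within 1.5 times except 5117 genes between root and leaf with pseudocount 5. Leaving out each treatment gave 7127 to 8060 for root and leaf, 17822 to 18095 for pollen and leaf, 17816 to 18150 for pollen and root. Leaving out each tissue gave 0 to 1 genes with a shared effect of nanoparticles, 0 to 0 of bulk CuO, 0 to 1 of CuSO4 and 0 to 1 of all copper materials, where the 1 gene came without pollen, which also raised the genes tested to 19054. All other alternatives gave 0 genes with a shared effect. Of the alternative log2 changes of named genes above 0 in both libraries, 39 moved by at least the SD over genes of the difference between the closest pair of libraries of the tissue, nearly all with another pseudocount, and 37 did not; none changed direction. Fitted changes of the named genes kept their direction and their side of the threshold. The alternatives for gene lists were not run, since no list could be applied. Low depth limits genes with low values in pollen most, where the estimated relative depth was lowest. No paired analysis was possible by replicate number because each tissue and treatment had 1 library; libraries of a tissue were paired only through the tissue block of the shared-effect fit.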

Other observations

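All tests and descriptions in this part were chosen after the data were seen, except the test of neighbouring genes, which was written before its result.

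The most abundant transcripts of leaf differed between control and both bulk CuO and CuSO4. Of the 100 genes with the highest FPKM in control leaf, 64 were lower by at least 1 on the log2 scale under bulk CuO and 10 higher, and 45 were lower and 14 higher under CuSO4. The reverse choice gave the reverse balance: of the 100 highest genes of the bulk CuO leaf, 62 were higher than in control leaf and 8 lower, and of those of the CuSO4 leaf 61 were higher and 2 lower. The direction therefore followed the library the genes were chosen in, and no general fall of abundant leaf transcripts is shown. Under nanoparticles 1 of the 100 highest genes of control leaf was lower and 1 higher. In root under bulk CuO, 30 of the 100 highest control genes were lower and 2 higher, and 33 of the 100 highest genes of the treated library were higher and 2 lower. In pollen 0 of the 100 highest control genes moved by 1 under any material.

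Genes past 2.3 were set beside the tissue in which a gene was higher than in both others. Genes higher in leaf than in both other tissues made up 39.8% of the genes higher in leaf under CuSO4 and 28.8% under bulk CuO, against 16.5% of all leaf genes kept. They also made up 24.6% of the genes lower in leaf under bulk CuO and 16.8% of those lower under CuSO4. Genes higher in root than in both other tissues made up 27.9% of the genes lower in leaf under CuSO4 and 17.1% of those lower under bulk CuO, against 11.98% of all. In pollen, genes higher in pollen than in both other tissues made up 10.5% of the genes higher under bulk CuO and 16.1% under CuSO4, against 20.9% of all. Under nanoparticles they made up 32.1%, 9 of 28 genes. These tissue classes come from the same libraries, so treated leaf values entered the leaf class, and the shares were not tested.

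Genes with neighbouring IDs did not move together beyond the range of shuffles. In leaf under bulk CuO, 63 of 15292 neighbouring pairs were past 2.3 in the same direction, against a mean of 50.1 and a highest value of 77 in 1000 shuffles of the genes, and 53 pairs were past it in opposite directions. The hypothesis that genes numbered next to each other changed together was not decided by these counts.

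Other splits of the libraries were run for the fitted comparisons, for tissues on the 8 libraries compared and without a treatment block, and for shared effects with tissue as a block. Over all splits into 4 and 4 libraries, 1 of the 35 splits of 8 libraries, the real one, gave as many genes for each pair of tissues. Every other split puts libraries of both tissues on each side, and these splits ignore that libraries are matched by treatment. They therefore do not exclude chance. The real splits gave 7558 genes for root and leaf, 18042 for pollen and leaf and 18407 for pollen and root, and the highest of the others gave 2, 0 and 0. If the libraries of a treatment are taken as pairs, 8 splits part every pair, too few for a share under 0.05; with treatment as a block the real ones gave 7376, 18033 and 18406 genes and the highest of the others 0, 0 and 0. For an effect shared by tissues, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real value was 0 for each material, a number that all 10 splits reach by necessity, with highest other values of 24 for nanoparticles, 206 for bulk CuO and 665 for CuSO4. For the mean of all copper materials the real value was 0 as well, all 100 splits drawn reach it by necessity, and the highest gave 920, so these counts say nothing about chance. These high values came from how the splits divide the tissues. In 6 of the 10 splits for each material both libraries of a tissue fell on the same side, so that with tissue as a block the contrast rested on 1 tissue, and the other 4, which parted every tissue, gave 0 genes. For the mean of all copper materials, the 29 splits that took 1 library from each tissue gave 0 genes, and the value of 920 came from the 71 others.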
